A study of Mus musculus with 2 samples.

How the data were processed

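ATAC-seq, in which the Tn5 transposase inserts sequencing adapters into accessible chromatin, was measured in megakaryocyte-erythroid progenitors (MEP) of male C57BL/6J mice aged 5 to 6 weeks. MEP are bone marrow cells that give rise to red cells and platelets. The labels give 50000 cells per library and call the 2 libraries biological replicates 1 and 2. Each has a biosample entry of its own, and both name the same donor entry, so whether they came from separate animals is not stated. There is 1 group, and the comparisons are between the libraries, between classes of region and between gene groups within the libraries. The label of replicate 1 names 2 sequencers and that of replicate 2 names none.

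The deposited files are peak lists in narrowPeak layout on mm10 (GRCm38), per the file headers and read-me texts. The deposited ratio column holds a fold per peak, read from its values and place as the fold over local background at the summit, and it was not scaled between libraries. The deposited −log10 p column holds the significance of each peak, which grows with library depth. The deposited score used here is the −log10 global irreproducible discovery rate (IDR), which measures how well the rank of a peak repeats between lists. The read-me texts say that lists came from filtered alignments and a file of excluded regions. The aligner, peak caller, their versions and the handling of the Tn5 offset are not given in the sources used here. Folds and significance values are the authors', were made by their caller, and serve here to describe, rank and filter peaks within a list.

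For each library the authors deposited an IDR-thresholded list, made from pseudoreplicates (random splits of 1 library), and a longer list called pseudoreplicated. For the libraries together they deposited a conservative list (IDR on the true replicates), a list thresholded on pooled pseudoreplicates, replicated and pseudoreplicated lists, and an older archived replicated list. Read counts were not used here, so the depth of the libraries is unknown and no interval that needs it is given. Wilson 95% intervals on shares of regions cover counting error only. Tests run over regions or genes, which are not replicates, so each p-value describes these libraries and not the spread between animals.

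The caller lists an interval several times when it has several summits, and 41.0% and 40.8% of lines in the IDR-thresholded lists of replicates 1 and 2 repeat an interval. Overlapping or touching peaks on the 21 main chromosomes were therefore merged into regions, each carrying the summit and fold of its strongest peak. No peak passed a chromosome end of the reference (0 in each list). Genes were the 21853 protein-coding genes of GENCODE M21 with 54361 transcription start sites (TSS). A region within 1 kb of a protein-coding TSS was a promoter region and any other was distal. A promoter was called accessible when a region of both IDR-thresholded lists overlapped the TSS ± 1 kb of any protein-coding transcript of the gene. Distal regions of a gene were those of the conservative list with a summit within 50 kb of its most upstream TSS. A distal region can count for several neighbouring genes, and the 50 kb window does not show which gene a region acts on.

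Promoter shares of 13 gene lists, with no gene in more than 1 list (0 repeats among 299 genes), were compared with all other genes by two-sided Fisher's exact tests. Odds ratios of gene lists have 0.5 added to each cell. Mean numbers of distal regions were compared with 10000 random lists of the same size, matched on quintile of the number of neighbouring TSS, where the smallest p is 0.0002 before adjustment. Differences between lists used Fisher's exact test or a permutation test with 100000 resamples. Motif consensus matches were counted in 201 bp around distal summits and in windows 500 bp to either side. The p compares each centre with 1 flank, taken alternately up- and downstream, by an exact McNemar test, and the larger p of the libraries was used. P-values below 1e-300 were set to that value. Adjusted p-values are Benjamini-Hochberg values over the 13 lists, 12 motifs or 3 list pairs, and under the other observations over the 5 hypotheses or the 117 pairs of list and motif, at a threshold of 0.05. The gene lists, motifs, tests, most alternatives and the rule for named genes were fixed before the data were examined.

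By that rule the text names 16 fixed genes (1 of them is not reported here), the 3 members of each list with most distal regions, up to 5 erythroid, megakaryocyte and transcription factor genes with no accessible promoter in either library, and the 2 other-lineage promoters of highest fold per list. It also names the 10 distal and 5 promoter regions highest in both libraries and, for each library, the 3 strongest regions absent from the longer list of the other. Further list members named as examples were chosen after their values were seen. The design foresaw fold values per library for the paired peaks. The file held −log10 p per library, so agreement and the ranking of those regions used −log10 p. Its pair of library columns carry no replicate numbers, and they are not assigned to a replicate here.

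The alternatives were other overlap rules, promoter and distal windows, peak lists, a stricter fold threshold (upper 50% of regions), GC-matched backgrounds, reversed motifs and leaving out each replicate. The archived list was added after seeing the data. Peaks on scaffolds outside the 21 chromosomes were left out of the comparisons. The steps were tested on simulated data. With 19579 planted regions merging returned 19579, a planted overlap of 80.8% came back as 80.8%, and 100 of 100 lists of 25 genes with a doubled mean were called against 6 of 100 unchanged lists at p below 0.05. The simulated counts were independent between genes, whereas real neighbours share regions, so these rates need not hold for the real lists. Planted motif shares came back within 1.15 percentage points for every motif. Work was done in Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9, and sequences were aligned with BLAST 2.17.0.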

Results

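The data describe accessible chromatin in 2 ATAC-seq libraries of mouse megakaryocyte-erythroid progenitors (MEP). Replicate 1 had 26353 accessible regions covering 16.7 Mb and replicate 2 had 28142 covering 17.9 Mb in their IDR-thresholded lists. The conservative list of both libraries held 46200 regions covering 28.3 Mb, or 1.07% of the genome outside assembly gaps, with a median width of 543 bp. The number of reads behind these lists is unknown. All coordinates are on mm10.

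Most accessible regions of either library were also accessible in the other. Promoter regions recurred more often than distal regions. The promoters of Cldnd1, Sel1l, which acts in protein quality control, and Tasp1, a protease gene, were among the strongest in both. Accessible regions of replicate 1 were overlapped by a region of replicate 2 in 86.2% of cases (22704 of 26353, Wilson 95% interval 85.7 to 86.6), and those of replicate 2 by replicate 1 in 80.7% (22702 of 28142, 80.2 to 81.1). After rotation of 1 list along each chromosome the shares were 1.4% and 1.31% on average over 100 rotations. Promoter regions recurred more often than distal ones, with 93.2% against 81.4% in replicate 1 (odds ratio 3.12, two-sided Fisher's exact p = 1.0e-174) and 92.2% against 73.6% in replicate 2 (odds ratio 4.21, p at most 1e-300). The promoters of Cldnd1, Bmt2, Sel1l, A930002H24Rik and Tasp1 had the highest mean significance of all promoter regions, between 129 and 131 on the −log10 p scale, with an SD between the libraries of 3.08 to 10.4 (n = 2). The Cldnd1 region (chromosome 16, 58727554 to 58728695) had a pooled fold of 15.6 and the Tasp1 region (chromosome 2, 140066092 to 140067391) one of 14.5.

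The gap between promoter and distal regions was present in each of 5 equal groups of regions ranked by fold. These groups were not matched on width, and overlap was counted from 1 bp. In replicate 1 regions with a promoter summit had a median width of 769 bp against 486 bp in introns. In the lowest group of replicate 2, 75.4% of promoter and 56.3% of distal regions recurred, and in the highest group 99.7% and 97.0%. Across 129103 paired peaks the significance of the libraries had a Spearman correlation of 0.768, and across 84797 merged regions 0.902. These correlations are across regions, which are not independent, so no p is given. Regions absent from the longer list of the other library were few, 147 for replicate 1 and 293 for replicate 2. The strongest were a Jarid2 intron (chromosome 13, 44869505 to 44869700, fold 10.5) and introns of Glce and Fbn2 for replicate 1. For replicate 2 they were a Tmem178 intron (chromosome 17, 80982518 to 80982760, fold 10.9) and intergenic regions near Sulf1 and Hyal6. The Jarid2, Fbn2 and Tmem178 regions are nevertheless in the conservative list, which was called on both libraries together.

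**Figure D1:**
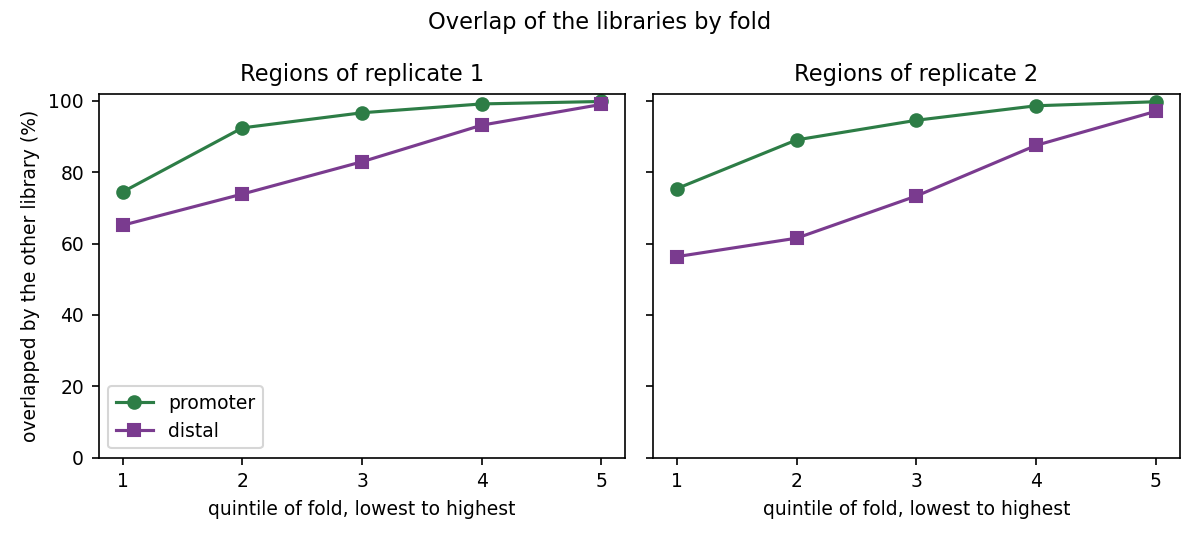
Share of regions of each library overlapped by a region of the other (vertical axis, percent) in 5 equal groups by fold (horizontal axis, lowest to highest), for promoter (circles) and distal regions (squares). In replicate 2 the distal share goes from 56.3% in the lowest group to 97.0% in the highest, and promoters lie above distal regions in every group of both libraries.

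Promoters took a far larger share of the accessible regions than of the genome. Intergenic sequence took a smaller share, and introns about the same share in the conservative list. By position, 27.8% of conservative regions had their summit within 1 kb of a protein-coding TSS (Wilson 95% interval 27.3 to 28.2), against 2.44% of the genome. Introns held 35.8% of summits and 34.4% of the genome, intergenic sequence 32.1% and 60.1%, and exons 4.37% and 3.02%. Promoter regions were also wider, with a median of 817 bp against 475 bp in introns. The promoter share was 38.9% and 36.9% in the IDR-thresholded lists of replicates 1 and 2, and it fell to 20.8% in the longer replicated list. The intron share lay below that of the genome in those IDR-thresholded lists (29.8% and 31.0%). In the replicated list it lay above (40.1%).

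Of the 10 distal regions of highest mean significance 8 were intergenic. The first lay on chromosome 12 (97061376 to 97061849), 1197903 bp from the nearest TSS, that of Galc, with a pooled fold of 27.4 and a −log10 p of 268 ± 5.44 (SD, n = 2). It was followed by intergenic regions on chromosome 5 (60042656 to 60043142, nearest gene G6pd2, fold 30.9) and chromosome 2 (69355474 to 69355729, 12985 bp from Abcb11, fold 41.5). The others lay nearest to Rpusd4, Gm8797, Nxph1, Gm5426, Chl1, Filip1l and Zfp960, where those inside Chl1 and Filip1l were intronic. Of the 10, 4 were absent from the conservative list and 5 aligned to mitochondrial DNA.

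Promoters of erythroid genes, such as those of globins and the erythropoietin receptor, were mostly accessible. Promoters of megakaryocyte and platelet genes were accessible less often than those of erythroid genes. Promoters of genes of granulocytes, lymphocytes, liver, neurons and muscle were mostly not called accessible. Without known depth, a missing call does not show a closed promoter. In both libraries 9988 of 21853 protein-coding genes (45.7%) had an accessible promoter. Erythroid genes stood above this share, with 20 of 24 (odds ratio 5.42, Fisher's exact adjusted p = 0.000686), as did genes of haem synthesis and iron handling with 20 of 24 (5.42, 0.000686) and housekeeping genes with 22 of 24 (10.7, 4.24e-05). When only the upper 50% of regions by fold was kept, these lists no longer passed (1.89, 1.12 and 1.60). Tfrc, encoding the transferrin receptor, had a promoter fold of 10.4 and 11 in replicates 1 and 2, and the globin genes Hbb-bs 9.58 and 9.67 and Hba-a1 9.10 and 7.98. Epor, the erythropoietin receptor gene, had 7.93 and 9.35, and Klf1, an erythroid transcription factor gene, 4.86 and 6.34. Of the erythroid genes, Alas2, Slc4a1, Hbb-bt and Tmod1 had no accessible promoter in either library. Of these, Hbb-bt (3.47 and 3.91) and Tmod1 (3.59 and 4.22) had a promoter region in both pseudoreplicated lists. Alas2 and Slc4a1 had none there either, but both had distal regions. Alas2 had 3, among them an intron region inside Alas2 and Apex2 (chromosome X, 150564621 to 150565269) with folds of 15.6 and 15.9 in the pseudoreplicated lists. Slc4a1 had 2, with pooled folds of 7.79 to 9.57, and 1 of them lay inside the gene. Hba-a1 and Hba-a2, and Hbb-bs and Hbb-bt, are near-identical pairs, so how reads were placed between members is uncertain.

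Megakaryocyte and platelet genes showed 6 of 25 accessible promoters, below all genes but not past the threshold (odds ratio 0.396, Fisher's exact adjusted p = 0.0501; without replicate 2 it passed, 0.365, 0.0302). It also passed with the upper 50% of regions by fold (0.0511) and with a 500 bp window (0.335). The 6 were Gp1ba, Nbeal2, Rab27b, Thbs1, Slc6a4 and Ltbp1, with folds from 5.04 to 7.68. Itga2b (platelet integrin), Gp6, Gp9, Gp1bb, Cd9 and Clec1b had none in either IDR-thresholded list, and P2rx1 had one in replicate 2 (fold 6.44). In the longer pseudoreplicated lists 15 of 25 had a promoter region in both libraries, among them Itga2b (3.04 and 3.86) and Gp9 (2.91 and 3.25), against 56.5% of all genes, so the direction turned (odds ratio 1.14, Fisher's exact adjusted p = 0.841). The difference between the erythroid and the megakaryocyte list was itself tested and was past the threshold (odds ratio 13.7, Fisher's exact adjusted p = 6.57e-05), as was that between the erythroid and the granulocyte and macrophage list (28.0, 4.28e-06). Megakaryocyte and granulocyte and macrophage promoters did not differ detectably (2.05, 0.463), but did in the pseudoreplicated lists, with 15 of 25 against 4 of 24 (6.72, Fisher's exact adjusted p = 0.00458).

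Haematopoietic transcription factor genes had 15 of 22 accessible promoters (odds ratio 2.46, Fisher's exact adjusted p = 0.0558; without replicate 2 it passed, 2.79, 0.0328). Nfe2 had promoter folds of 8.94 and 8.48, Runx1 6.63 and 6.23, Gata1 4.69 and 5.12, Zfpm1 4.58 and 4.82 and Tal1 3.75 and 3.77. The Runx1 value comes from a TSS more than 50 kb from the most upstream one. The region behind the Gata1 call (chromosome X, 7967767 to 7968639) lay at a TSS inside the gene, 9.6 kb downstream of the most upstream annotated TSS. Cbfa2t3, Erg, Fli1, Gata2 and Gfi1b had no accessible promoter in either library, while in the pseudoreplicated lists 21 of 22 members had one in both (Fisher's exact adjusted p = 0.000227), Gata2 being the exception. When only the upper 50% of regions by fold was kept, the odds ratio of this list turned to 0.182 (Fisher's exact adjusted p = 0.0380). Among stem and multipotent progenitor genes 6 of 20 had an accessible promoter (odds ratio 0.532, Fisher's exact adjusted p = 0.183), and in the pseudoreplicated lists 14 of 20, which turned the direction (1.72, 0.286). Kit, the stem cell factor receptor gene, had 6.79 and 6.52 and Egr1 5.07 and 5.37, and Cd34, Flt3 and Ly6a had none, of which Cd34 and Flt3 had one in both pseudoreplicated lists.

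Genes of other blood lineages mostly had no accessible promoter. Granulocyte and macrophage genes had 3 of 24 (odds ratio 0.193, adjusted p = 0.00169), mast cell, basophil and eosinophil genes 2 of 19 (0.169, 0.00354), B cell genes 3 of 20 (0.237, 0.00777) and T and NK cell genes 2 of 24 (0.132, 0.000515), all by Fisher's exact test. With the upper 50% of regions by fold the mast cell (0.372), B cell (0.521), neuron (0.289) and muscle lists (0.424) no longer passed. The exceptions included lineage transcription factor genes, a grouping that was not tested. Other such genes of these lists, among them Cebpe, Gfi1, Tcf7, Bcl11b, Eomes and Tbx21, had no accessible promoter in either library. Cebpa had promoter folds of 5.71 and 7.38, Spi1 5.42 and 4.56, Mitf 11.3 and 11.4, Ebf1 9.94 and 11.2 and Gata3 8.05 and 8.92. Cr2, a B cell complement receptor gene, had 14.1 and 12.5, Il1rl1 7.73 and 8.48, Cd3d 5.09 and 7.54 and Fcgr3 3.66 and 3.79. The regions behind the values of Cd3d, Gata3 and Spi1 lie at other TSS, 4.8, 10.3 and 14.3 kb downstream of the most upstream one. Of the outgroups, hepatocyte genes had 1 of 25 (Fisher's exact adjusted p = 4.24e-05), neuron genes 4 of 24 and muscle genes 4 of 24 (both adjusted p = 0.00543). In both pseudoreplicated lists the counts were 4 of 24 for granulocyte and macrophage genes and 5 of 19 for mast cell genes. They were 6 of 20 for B cell and 4 of 24 for T and NK cell genes. Hepatocyte, neuron and muscle genes had 2 of 25, 7 of 24 and 5 of 24 there, against 56.5% of all genes. The muscle gene Mylpf (6.47 and 7.83) has a TSS of Tbc1d10b within 1 kb.

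**Figure D2:**
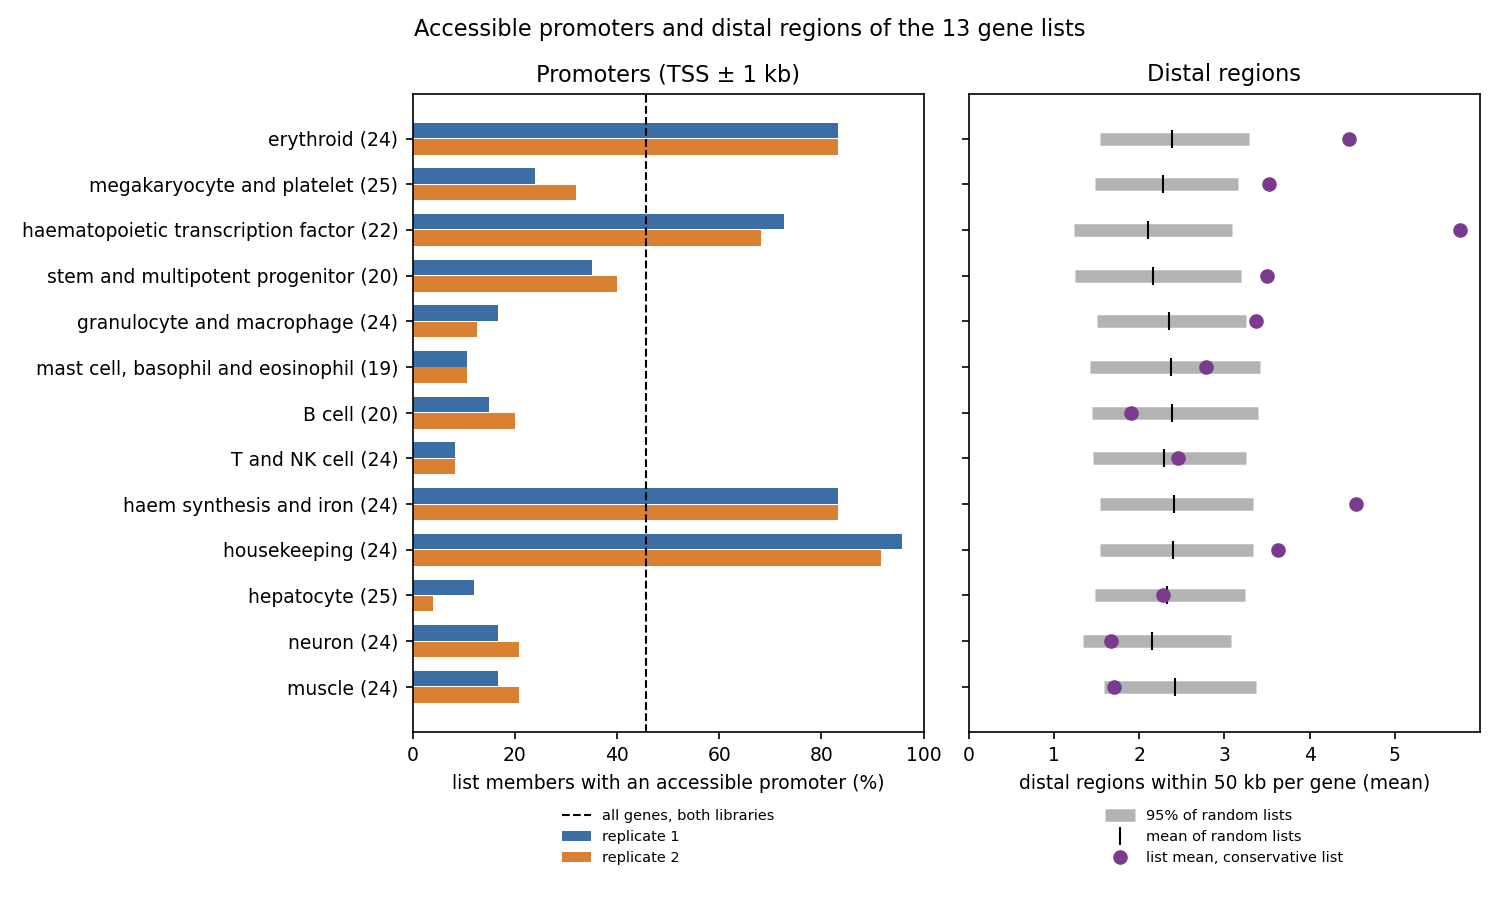
Left, share of each gene list with an accessible promoter (horizontal axis, percent) in replicates 1 and 2 (bars), with the share of all genes in both libraries (dashed line, 45.7%); right, mean number of distal regions within 50 kb per gene (points) with the mean and central 95% of 10000 random lists (ticks and grey bars). Erythroid genes reach 20 of 24 promoters and megakaryocyte genes 6 of 25 in both libraries, and transcription factor genes have 5.77 distal regions per gene against 2.10 in random lists.

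Haematopoietic transcription factor genes were surrounded by the most distal accessible regions in the conservative list, though not when only strong regions were kept or in replicate 2 alone. Erythroid and haem and iron genes followed. Genes of lymphocytes, liver, neurons and muscle did not stand out from random genes. Transcription factor genes had the most, 5.77 per gene against 2.10 in random lists (2.74-fold, central 95% of random lists 1.23 to 3.09, permutation test of gene labels, adjusted p = 0.000867). With the upper 50% of regions by fold this ratio was 1.12 and did not pass (permutation adjusted p = 0.804), and those of haem and iron (1.47) and housekeeping genes (1.61) did not pass either. In replicate 2 alone erythroid (3.21) and haem and iron genes (3.00) had more distal regions per gene than transcription factor genes (2.95). Haem and iron genes had 4.54 (1.89-fold) and erythroid genes 4.46 (1.87-fold), both with a permutation adjusted p of 0.000867, which comes from the smallest p that the random lists can give (0.0002). Megakaryocyte genes had 3.52 (1.55-fold), stem and progenitor genes 3.50 (1.62-fold) and housekeeping genes 3.63 (1.51-fold), all with a permutation adjusted p of 0.0316. Neighbouring members of a list, such as Hba-a1 and Hba-a2 or Hbb-bs and Hbb-bt, count the same regions more than once. The random lists were not matched on such neighbours, so the p-values of the lists may be too small. Granulocyte and macrophage genes had 3.38 (1.44-fold, permutation adjusted p = 0.0613), and passed with replicated peaks (1.45), with matching on accessible promoters (1.71) and with the archived list (1.32). The lists of mast, B and T cells and of the outgroups did not pass the threshold (ratios 0.705 to 1.18), and that of mast cell genes fell below 1 without either replicate (0.670 and 0.738). The number of distal regions did not differ detectably between erythroid and megakaryocyte genes (0.938 more, permutation test adjusted p = 0.313), between erythroid and granulocyte and macrophage genes (1.08 more, 0.313) or between megakaryocyte and granulocyte and macrophage genes (0.145 more, 0.877). The result for the stem list was not past the threshold with either replicate alone (1.73-fold and 1.69-fold, permutation adjusted p = 0.0615 and 0.0707). That for the megakaryocyte list was lost without replicate 1 (1.59-fold, permutation adjusted p = 0.0707), as was that for housekeeping genes (1.48-fold, 0.138). A 100 kb window also ended the calls for megakaryocyte (1.39) and stem genes (1.45), and assignment by nearest TSS those for megakaryocyte (1.81), haem and iron (1.85) and housekeeping genes (1.72).

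Among transcription factor genes Zfpm1, encoding the GATA1 partner FOG1, had 11 distal regions, 8 of them inside the gene, with pooled folds of 2.93 to 5.44. Cbfa2t3 had 10, Fli1 9, Gfi1b 8, Runx1 7 (all intronic), Tal1 6, Gata2 5, Gata1 4 and Nfe2 3. A GATA site lay in 9 of those of Cbfa2t3, 6 of Zfpm1, 5 each of Fli1 and Gfi1b and 4 of Runx1. The counts were 3 for Tal1, 2 each for Gata2 and Gata1 and 0 for Nfe2. Over the whole list the share was 46.7% of 120 regions against 42.4% elsewhere (Fisher's exact adjusted p = 0.886). A Gata2 intron region (chromosome 6, 88203035 to 88203634), 9.3 kb downstream of the TSS, held an E-box-GATA composite site and had folds of 4.56 and 3.69 in the pseudoreplicated lists. Upstream of Gata1 a region on chromosome X (7993105 to 7993782) with a composite site had 11.1 and 11.

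Around erythroid genes, Aqp1, encoding a water channel of the red cell membrane, had 12 distal regions, 9 with a GATA site. Hba-a1 (chromosome 11, 32283511 to 32284465) had 9, of which 6 lay inside Nprl3, the neighbouring gene whose introns hold the alpha-globin enhancers. The strongest was in a Nprl3 exon (32255877 to 32256820), 27.2 kb upstream, with folds of 9.01 and 11.4. An intron region 37.7 kb upstream (32245332 to 32246085) held a composite site and had 8.08 and 9.02. Hbb-bs (chromosome 7, 103826534 to 103828096) had 8, among them a region 31.2 kb upstream (103858788 to 103859542) with 8.90 and 9.36, on the side of the cluster that carries the locus control region. Epor had 3 and Klf1 5. GATA sites lay in 5 regions of Hba-a1, 6 of Hbb-bs, 1 of Epor and 0 of Klf1. Over the erythroid list the share was 50.5% of 95 regions against 42.4% elsewhere (Fisher's exact adjusted p = 0.801 over all pairs of list and motif). Among iron and haem genes Glrx5 had 12, Fech 9 and Slc48a1 9.

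**Figure D3:**
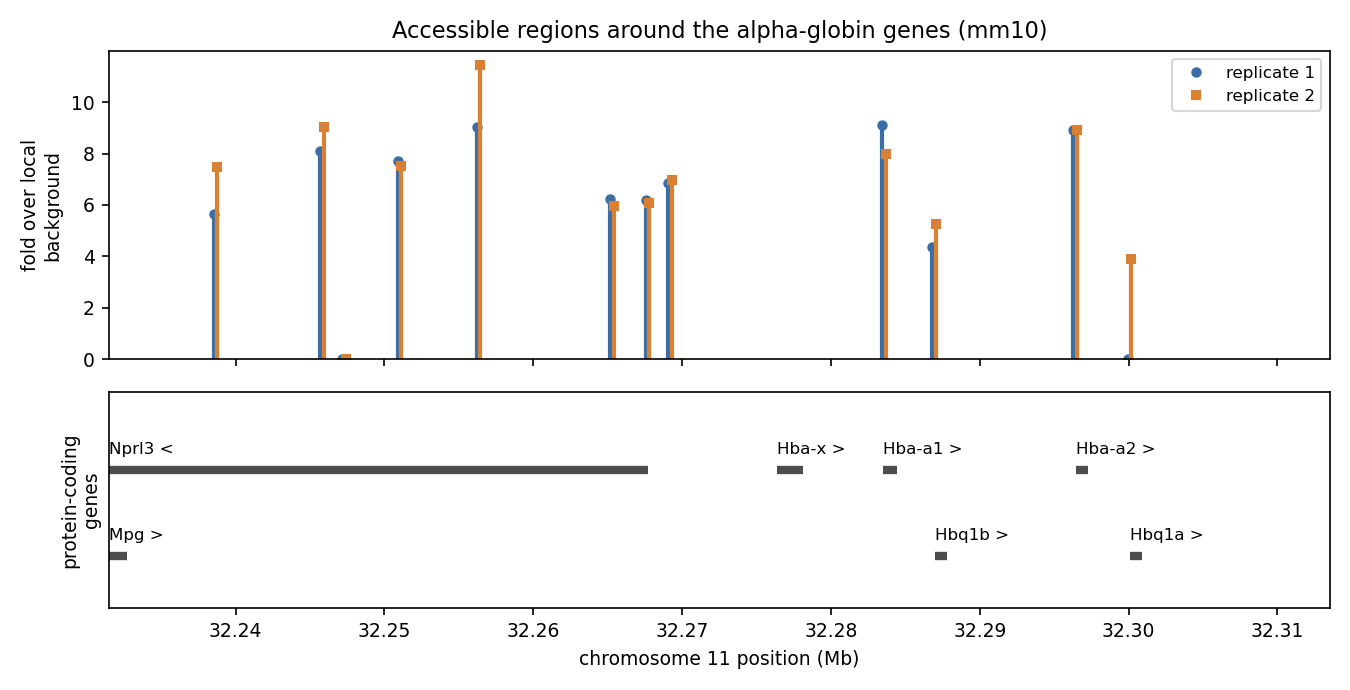
Regions of the conservative list around the alpha-globin genes on chromosome 11 (horizontal axis, Mb), with the fold in the pseudoreplicated list of each library (vertical axis, stems ending in circles for replicate 1 and squares for replicate 2; 0 where the library lists no peak). The lower panel shows protein-coding genes with their direction. The highest stem of replicate 2 (11.4) lies in Nprl3, and the promoter regions of Hba-a1 have folds of 9.10 and 7.98.

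In the megakaryocyte list Nbeal2, Gp9 and P2rx1 had 6 distal regions each, Cd9 5 and Itga2b 4. The Itga2b intron region (chromosome 11, 102466901 to 102467658) had 7.17 and 7.51. In the stem and progenitor list Egr1 and Flt3 had 8 each, Ly6a 6, Cd34 5 and Kit 3. Some other-lineage genes with no promoter region in the IDR-thresholded lists also had many, such as Klrb1c with 10, Ccr3 with 8, Elane, Prtn3 and Cd247 with 6 each, and Eomes, Dntt, Blnk, Prg2 and Prg3 with 5 each, where Blnk, Prg2 and Prg3 had a promoter region in both pseudoreplicated lists. Fcer2a, with a promoter region in replicate 2 alone (7.81), had 5, and Fcgr3, with an accessible promoter, had 13. Neighbours share regions, Elane with Prtn3 and Prg2 with Prg3 among them. Of the outgroups, Hpd, Pck1, Mylpf and Tnnc2 had 7 each, Tnni2 and Tubb3 6, Eno2 and Slc32a1 5 and Hnf4a 4, and of housekeeping genes Actb had 8 and B2m and Eef1a1 6.

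Sites of GATA factors, which drive erythroid and megakaryocyte genes, were enriched at the summits of distal regions. The joint site of TAL1 and GATA1 and the site of CTCF had the highest ratios of summit to flank share, and both were rare in the flanks. Sites of CEBP factors, which act in granulocytes, were not enriched over the flanks. GATA sites were present in 47.5% of distal regions of replicate 1 (Wilson 95% interval 46.8 to 48.3) and 46.7% of replicate 2 (46 to 47.5), against 19% and 18.9% in the flanks, a mean ratio of 2.49 (exact McNemar adjusted p at most 6.0e-300). The E-box-GATA composite, the site bound by the TAL1 and GATA1 complex, was in 7.12% and 6.85%, against 0.390% and 0.416% in the flanks (ratio 17.4, exact McNemar adjusted p = 1.25e-259). CTCF sites, bound by the insulator protein of that name, were in 8.43% and 9.03%, against 0.260% and 0.244% in the flanks (ratio 34.8, exact McNemar adjusted p at most 6.0e-300). Ratios of motifs with unlike flank shares do not rank their strength, since a site in 19% of flanks has less room to rise. KLF sites had a ratio of 2.20 (exact McNemar adjusted p = 3.23e-118), PU.1 sites 1.60 (3.08e-05), NFE2 and AP-1 sites 1.55 (1.20e-19), RUNX sites 1.46 (1.61e-58) and ETS sites 1.45 (3.97e-11). At summits KLF sites (15.8% and 14.9%) exceeded their reversed consensus (9.10% and 8.64%), which in turn exceeded the KLF flank share (6.96% and 7.02%). The reversed consensus of the other 4 motifs at summits also exceeded their flank share. These 5 ratios therefore do not separate the site from base composition at summits. NRF1 sites had a ratio of 6.27 (exact McNemar adjusted p = 4.63e-08) but were in 0.310% and 0.292% of regions. CEBP sites did not differ detectably (ratio 1.00, exact McNemar adjusted p = 0.959), nor did MEF2 (0.928, 0.959) or HNF4 (0.715, 0.225), where HNF4 passed in replicate 2 alone (0.685, adjusted p = 0.00293). The McNemar p uses 1 flank per region and the ratio uses both, so the HNF4 p in replicate 2 does not test its ratio. Against the reversed consensus in the same windows CEBP sites did pass (ratio 2.54, Fisher's exact adjusted p = 4.03e-13). The flank shares of CEBP sites (1.20% and 1.22%) also exceeded the reversed share at summits (0.462% and 0.499%). This pass therefore does not show enrichment at summits.

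**Figure D4:**
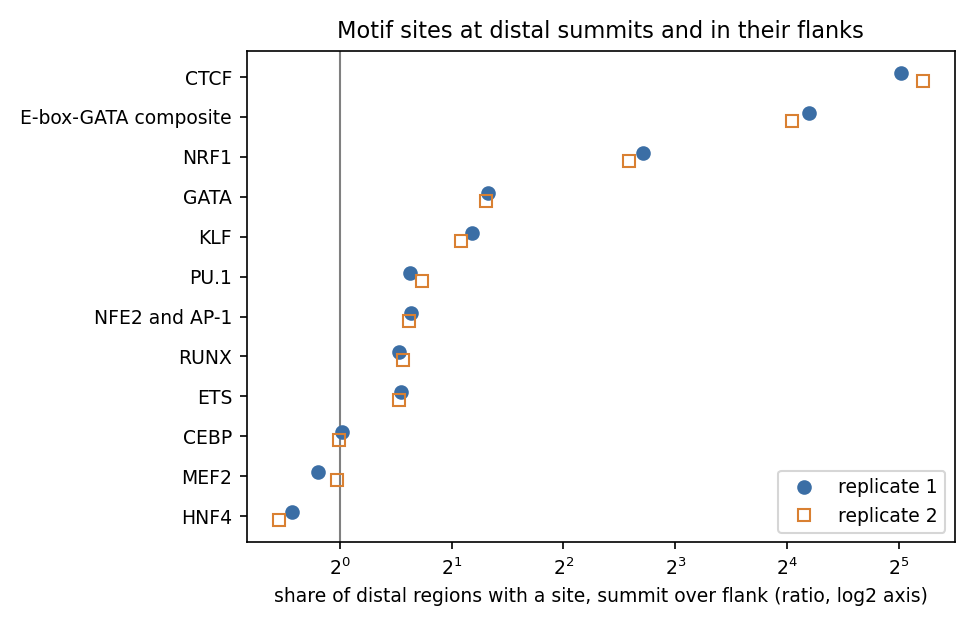
Ratio of the share of distal regions with a motif site at the summit to the share in the flanks (horizontal axis, log2 scale) for 12 motifs in replicate 1 (filled circles) and replicate 2 (open squares); the vertical line marks a ratio of 1. CTCF (34.8 on average) and the E-box-GATA composite (17.4) lie farthest to the right and CEBP lies at 1.00.

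Sites of GATA factors, CTCF and RUNX factors were more frequent in distal than in promoter regions. Sites of KLF, ETS and NRF1 factors were more frequent in promoter regions. In the conservative list GATA sites were in 42.4% of 32778 distal and 11.1% of 13422 promoter regions (odds ratio 5.89, Fisher's exact adjusted p at most 6.0e-300), the composite in 5.29% and 1.10% (5.04, 1.45e-118), CTCF in 10.2% and 1.76% (6.34, 5.57e-264), and NFE2 and AP-1 in 5.64% and 2.54% (2.29, 4.16e-51). RUNX sites were also more frequent in distal regions (24.6% against 16.3%, odds ratio 1.68, Fisher's exact adjusted p = 3.03e-88). KLF (13.9% and 37.3%, odds ratio 0.272), ETS (5.01% and 10.7%, 0.441) and NRF1 sites (0.223% and 4.17%, 0.0513) were more frequent in promoter regions, with adjusted p at most 6.0e-300, 1.69e-100 and 4.90e-218. PU.1 (odds ratio 1.18, Fisher's exact adjusted p = 0.0302), HNF4 (1.84, 0.0302) and MEF2 sites (1.60, 0.0324) were slightly more frequent in distal regions, though HNF4 (1.36) and MEF2 (1.4) did not pass with a 2 kb promoter window, and CEBP sites did not differ detectably (1.15, 0.169). These tests compare shares of regions and were not matched on base composition. Over their own flanks, KLF sites had ratios of 2.05 in distal and 2.70 in promoter regions, ETS sites 1.47 and 3.32, and NRF1 sites 6.35 and 10.8. GATA sites had 2.26 and 0.866 and CTCF sites 51.0 and 12.1. HNF4 (0.770 and 0.372) and MEF2 sites (0.973 and 0.683) lay below their flanks in both classes, which was not tested.

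Promoters of X-linked genes were accessible less often than those of autosomal genes, in male cells with a single X chromosome. Those that were accessible had higher folds. Of 948 X-linked genes 310 had an accessible promoter (32.7%), against 9675 of 20722 autosomal genes (46.7%, odds ratio 0.555, Fisher's exact p = 1.3e-17). The median fold of accessible X-linked promoters was 10.5 against 8.33 in replicate 1 and 10.9 against 8.77 in replicate 2, a difference that was not tested. Autosomal genes matched on promoter GC and CpG content had 37.1% accessible promoters, which left a smaller gap of 4.44 percentage points. Of 183 genes on the Y chromosome 3 had an accessible promoter.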

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

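Chosen only after the result was seen were the split of the strongest distal regions by mitochondrial match, both mitochondrial tests, the test of reads in a single library and the test of depth on the X chromosome.

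The libraries' paired peak output, of which the comparisons used merged regions and the strongest peaks, held 305 peak pairs past the IDR threshold that were absent from the conservative list. Of these, 139 lay on 17 scaffolds outside the 21 chromosomes and 166 in 82 regions on the chromosomes, with a highest fold of 37.4. The archived replicated list, used only for alternatives, held 111338 regions (55.3% of 201500) that overlap no region of the current replicated list. Their median fold was 3.12 against 5.38 for the others, and 8.02% against 23.1% were promoters. Both were singled out as signal in data mostly outside the comparisons, although 4 of the 10 strongest distal regions named in the results are absent from the conservative list, among them the region with the fold of 37.4, nearest to Gm8797. The read-me texts name a file of excluded regions, and whether it accounts for the absence of the 305 pairs was not tested.

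Of the 10 strongest distal regions, 5 aligned to mitochondrial DNA, against 22 of 32778 distal regions of the conservative list (0.0671%), and the 4 regions of highest fold in that list all did. Over the 23 matching regions the fold rose with identity to mitochondrial DNA (Spearman 0.515, permutation p = 0.0162). The 23 include the 5 strongest regions that prompted the test, so the correlation gives no separate support. A further 5 of the 23 lie close together on chromosome 4 and are not independent. Reads of mitochondrial DNA placed on nuclear copies may account for the 5 strongest matching regions, which this test cannot decide. The identity test replaced an earlier one on the number of matching regions, which the count of 5 of 10 left undecided. Reads of mitochondrial DNA placed on nuclear copies are argued against as the source of all 10, since 5 of the 10 had no such alignment at a BLAST E of at most 1e-10. For these 5, sequence present in several near-identical copies in the nuclear genome stays open, since 2 had a further nuclear alignment at 90% identity over 80% of their length and 3 had none, and no biological explanation was tested.

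Promoters of 15 of 25 megakaryocyte and platelet genes were in both pseudoreplicated lists against 6 in the IDR-thresholded lists, and the promoters of transcription factor genes had low folds. Too few reads in a single library may contribute to the first, since 5 of the 9 gained promoters were in the conservative list made from both libraries, but the share among all genes was higher (1776 of 2367), so this does not single out the list. Neighbourhoods dense in accessible regions are argued against as the whole cause. Lists matched on distal regions had higher median folds, with a difference of -2.46 for megakaryocyte genes (15 promoters) and -2.28 for transcription factor genes (21 promoters). Both lists lay outside the central 95% of random lists in both libraries. A partial contribution stays open, since the matched medians lay below those of all promoters in both pseudoreplicated lists (7.67 and 8.10 in replicates 1 and 2). They were 7.51 and 7.95 for megakaryocyte genes and 7.02 and 7.38 for transcription factor genes. The cause of the low folds stays open, and no biological explanation was tested.

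X-linked promoters were accessible less often but at a higher fold than autosomal ones. At equal fold the −log10 p of X-linked peaks was lower, with a median ratio of 0.819 over fold bins (0.802 and 0.836 in replicates 1 and 2), so lower read depth on the single X chromosome of male cells may contribute. Matching autosomal genes on promoter GC and CpG content lowered their accessible share from 46.7% to 37.1%, against 32.7% for X-linked genes. Promoter content thus went with the larger part of the gap, and 4.44 percentage points remained. Whether GC and CpG content of X-linked promoters is a cause stays open. No biological explanation was tested.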

How the results depend on the processing

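Only the alternatives with the archived list were chosen after seeing the data. The mean overlap of both directions (83.4%) ranged from 80.2% to 84.3% under 3 alternatives. It moved by less than 1 SD of the 2 directional shares, which reflects unlike list sizes and is no spread between libraries. Promoter against distal recurrence (odds ratios 2.54 to 4.21) and the X-linked deficit (0.519 to 0.557, none of them matched on GC and CpG) kept direction and side of the threshold under 3 each. Gene lists did so in 76 promoter and 103 distal results, list differences in 20, and motifs in 64 distal and 22 promoter against distal results. Directions turned with neither value past the threshold for megakaryocyte (1.14) and stem promoters (1.72) with pseudoreplicated peaks. So did distal ratios with the upper 50% of regions by fold for mast cell (0.945), B cell (1.25), T and NK cell (0.746) and hepatocyte genes (1.17), and for hepatocyte genes by nearest TSS (1.02) and matched on accessible promoters (1.24). CEBP turned with the upper 50% (0.901) and pseudoreplicated peaks (0.975), and HNF4 against the reversed consensus (1.39). With the upper 50% of regions by fold, the promoter odds ratio of transcription factor genes reversed to 0.182, those of the erythroid (1.89), mast cell (0.372), B cell (0.521), haem and iron (1.12), housekeeping (1.60), neuron (0.289) and muscle lists (0.424) no longer passed, and that of megakaryocyte genes did (0.0511). Distal ratios of transcription factor (1.12), haem and iron (1.47) and housekeeping genes (1.61) no longer passed there. With pseudoreplicated peaks the transcription factor promoters (11) and the megakaryocyte against granulocyte and macrophage difference (6.72) passed, as did megakaryocyte promoters with a 500 bp window (0.335). Distal ratios no longer passed with a 100 kb window for megakaryocyte (1.39) and stem genes (1.45), by nearest TSS for megakaryocyte (1.81), haem and iron (1.85) and housekeeping genes (1.72), with the list of pooled pseudoreplicates for stem (1.56) and housekeeping genes (1.44), without matching for stem genes (1.52), and matched on accessible promoters for housekeeping genes (1.25). For granulocyte and macrophage genes they passed with replicated peaks (1.45), that matching (1.71) and the archived list (1.32). Without 1 replicate, promoter odds ratios ranged from 0.365 to 0.527 for megakaryocyte and 2.25 to 2.79 for transcription factor genes, passing without replicate 2. Distal ratios ranged from 1.59 to 1.83 for megakaryocyte, 1.69 to 1.73 for stem, 1.48 to 1.70 for housekeeping and 0.670 to 0.738 for mast cell genes, which reversed. The HNF4 ratio ranged from 0.685 to 0.745 and that of CEBP from 0.993 to 1.02, reversed without replicate 1. Against the reversed consensus MEF2 reversed (2.67) and CEBP passed (2.54), and CTCF had no reversed match and so no ratio. The flank shares of CEBP, MEF2 and HNF4 also exceeded their reversed shares at summits, so these changes do not show enrichment at summits. With a 2 kb promoter window the HNF4 (1.36) and MEF2 (1.4) differences no longer passed. The promoter share moved to 20.8% with replicated peaks, 14.0% with the archived list, and 24.0% and 31.8% with 500 bp and 2 kb windows. The correlation moved to 0.746 past the IDR threshold and 0.902 over merged regions. Of distal counts of named genes 211 moved and 197 did not. The cause of these changes was not tested. Depth is unknown, so what it limits was not assessed.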

Other observations

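Only the test of all motifs near all lists was chosen after the result was seen, and the rule that an interval must exclude 1 before the GATA, ETS and CEBP hypotheses count as contradicted was also set then. Distal regions near erythroid genes carried a GATA site in 50.5% of 95 regions against 42.4% elsewhere (odds ratio 1.39, 95% interval 0.930 to 2.07, Fisher's exact adjusted p = 0.198), so whether they are enriched cannot be decided at this number of regions. The same holds for ETS sites near megakaryocyte genes, in 1 of 82 regions (odds ratio 0.348, interval 0.0692 to 1.75, Fisher's exact adjusted p = 0.244), and for CEBP sites near granulocyte and macrophage genes, in 1 of 73 (1.66, 0.329 to 8.39, 0.595). Among all 117 pairs of list and motif, 1 had an adjusted p under 0.05, GATA sites near T and NK cell genes, in 17.5% of 57 regions against 42.5% elsewhere (odds ratio 0.30, Fisher's exact adjusted p = 0.00944).

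Distal regions in the IDR-thresholded lists of both libraries carried GATA sites more often than those in 1 of these lists, as the hypothesis held, with an odds ratio of 1.53 on average (Fisher's exact adjusted p = 7.52e-24, 49.5% against 39.0% in both libraries) and 1.47 and 1.61 within quintiles of fold. The same hypothesis for CTCF sites did not hold, since the odds ratio was 0.568 (Fisher's exact adjusted p = 1.07e-13) and the share fell from 12.1% to 7.60% in replicate 1 and from 13.2% to 7.55% in replicate 2 in regions of both lists. Nearly all regions of 1 list are in the longer list of the other library (99.4% and 99.0% of all regions), so these tests concern the IDR threshold and not presence in a single library.

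Of all genes, Ccr1 and Abt1 had the most distal regions within 50 kb, 16 each, and 28.4% of genes had none.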
